A study of Mus musculus with 9 samples.

How the data were processed

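RNA was measured in 9 libraries of brain tissue from adult male mice of 3 genotypes, with 3 libraries per genotype: wild type (labelled B6N), Tfap2a+/- and Tfap2b+/-. Per the labels' protocols, between 20 and 80 mg of tissue was homogenised, and 500 ng of total RNA per sample went through selection of polyadenylated RNA, random priming and second-strand synthesis with dUTP, which keeps the strand. The libraries were amplified with 11 PCR cycles and sequenced as read pairs of 75 bp. The part of the brain that was taken is not given in the sources used here, nor is the construction of either knockout allele. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

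The authors deposited 1 table of whole-number counts per library, in the layout of STAR's gene counts, with counts per gene for unstranded, forward-strand and reverse-strand reading and 4 rows that name no gene. The submitters' processing notes name cutadapt 2.4, STAR 2.6.1d, edgeR and the build GRCm38.p6. The annotation release is not given in the sources used here. Of 54446 gene identifiers, 54409 were found in GENCODE M21, on the same build, ignoring version numbers. The other 37 kept their identifiers as names. Coordinates are from that annotation.

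The reverse-strand counts were used, as the dUTP kit requires. Forward-strand counts made up 4.16% to 4.94% of the stranded gene counts. Counts in genes came to 21946800 to 29214975 per library, of 26691820 to 36180085 fragments, so a gene with a count of 0 in a library may be present at up to 0.101 to 0.141 CPM (counts scaled to a common library size), the level of 3 counts. Such floors cover counting error only, since PCR copies cannot be recognised. The rows that name no gene stayed out of library sizes and tests. Reads outside annotated exons on the sense strand made up 7.30% to 11.8% of fragments, reads at several genomic positions 5.33% to 6.20%, unmapped reads 1.21% to 1.74% and reads shared by overlapping genes 1.10% to 1.21%. Reads at several positions are not counted by STAR, so counts of genes with near-identical copies are uncertain. No pair of libraries of 1 genotype agreed within sampling noise: the smallest chi-square per degree of freedom was 20.6.

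Genes were filtered with filterByExpr, which left 17355, and tested in edgeR 4.0.16 (R 4.3.3) with TMM normalisation and the quasi-likelihood F-test, with genotype as the only term and all 9 libraries sharing 1 estimate of spread. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2 scale with their standard error (SE), and CPM values are TMM-scaled and given as mean ± SD. Gene lists fixed beforehand were tested as 37 sets with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera was repeated with an estimated correlation and beside fry. A list was described as higher or lower where camera's adjusted p over the 37 lists was under 0.05. The preset treats members as nearly independent, but the estimated correlation was 0.68 for striatal and 0.99 for myelin genes. No list was called with estimated correlations or by fry's directional test, so these words give directions and not established changes. A score per library was the mean over the members of a list of log2 CPM minus the gene's mean over the 9 libraries. Single values were compared with two-sided exact permutation tests, which cannot go below p = 0.1 for 3 against 3 libraries.

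Named genes followed a rule: the Tfap2 genes, the Y-linked and Xist checks, Nnt and Gabra2, the 10 genes of smallest p in each comparison (because fewer than 10 passed the adjusted p), and up to 4 members of smallest p from each list that camera called, or up to 2 from another list that is described. Names outside it are said to have been chosen after their values were seen. Design, gene lists, tests, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, its size factors in edgeR, other filters, unstranded counts, the replicate number as a block, only the libraries of the 2 genotypes compared, a robust fit, a surrogate variable from sva 3.50.0 and each library left out in turn. Leaving a library out keeps 2 in its group, and the fit still pools the spread of all groups.

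The tests were tried on simulated counts for the 17355 genes, 50 of them changed at each of 4 fold sizes, drawn with the means, library sizes and spread of these samples. In the design of the Tfap2a comparison, edgeR recovered 18% of genes changed by 1.5-fold, 50% by 2-fold, 78% by 4-fold and 88% by 8-fold, and called 5 unchanged genes. For the Tfap2b comparison the shares were 6%, 50%, 78% and 90%, with 3 unchanged genes called. DESeq2 called 39 and 33 unchanged genes in the same simulations. When the circadian clock genes alone were moved 2-fold, camera called that list in both designs, and 1 and 0 of the 36 other lists. Each gene was drawn independently of the others, so these counts do not show how often camera calls unchanged lists whose members vary together.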

Results

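Polyadenylated RNA of the brain was sequenced from adult male mice aged 3 to 4 months that were labelled as wild type (B6N) or as carrying 1 inactivated copy of Tfap2a or of Tfap2b. These genes encode AP-2 alpha and AP-2 beta, DNA-binding transcription factors known for their roles in the neural crest and in the developing nervous system. Each genotype had 3 libraries. The counts in genes per library ran from 21946800 to 27051802 in wild type, from 22496880 to 28517579 in Tfap2a+/- and from 26216100 to 29214975 in the libraries labelled Tfap2b+/-. The series compares each heterozygote with wild type, and both heterozygotes can be compared with each other.

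The targeted genes came first, as a check of the labels. Tfap2a (ENSMUSG00000021359.16, chromosome 13, 40715302 to 40738376, GRCm38) was close to the limit of detection, at 0.536 ± 0.244 CPM in wild type and 0.376 ± 0.133 CPM in Tfap2a+/- (SD, n = 3). Its log2 fold was -0.49 ± 0.80 (SE), with a 95% interval from -2.31 to 1.33, which holds both no change and the loss of 1 copy (edgeR adjusted p = 0.999). The fold was -0.18 without wild-type library 3 and -0.82 without wild-type library 2. Tfap2b (ENSMUSG00000025927.13, chromosome 1, 19208914 to 19238576) went against its label. It stood at 2.25, 0.715 and 14.8 CPM in wild-type libraries 1 to 3 and at 32.9, 8.90 and 5.81 CPM in the libraries labelled Tfap2b+/-. The log2 fold of 1.42 ± 0.98 (SE) was not called (edgeR adjusted p = 0.60), and in the fit of all libraries its 95% interval ran from -0.80 to 3.64. Without library 1 of that group the log2 fold was 0.32, without wild-type library 2 it was 0.90, and without wild-type library 3 it was 3.44. It turned to -0.21 without wild-type library 2, Tfap2a+/- library 1 and library 1 labelled Tfap2b+/- together, the 3 marker-high libraries, chosen after seeing the data for the highest choroid plexus or hindbrain scores. These include the lowest wild-type value of Tfap2b and the highest in the libraries labelled Tfap2b+/-, so leaving them out could only lower the fold. Counts cover the whole gene, and the altered part of the allele is not given in the sources used here, so RNA from an inactivated copy would be counted too. Every direction below for this group therefore refers to the libraries labelled Tfap2b+/-. Among the other family members, Tfap2d, which lies next to Tfap2b on chromosome 1 (19103022 to 19166346), had 4.00 ± 3.48 CPM in the libraries labelled Tfap2b+/- and 0.651 ± 0.523 CPM in wild type (log2 fold 2.58 ± 0.88, edgeR adjusted p = 0.42, higher in 3 of 3 libraries, log2 fold 1.63 without library 1 labelled Tfap2b+/-). Tfap2c was at 0.103 ± 0.141 CPM in wild type, 0.0263 ± 0.0233 CPM in Tfap2a+/- and 0.263 ± 0.426 CPM in the libraries labelled Tfap2b+/-. Tfap2e had no count in the 9 libraries, which allows up to 0.101 to 0.141 CPM.

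**Figure D1:**
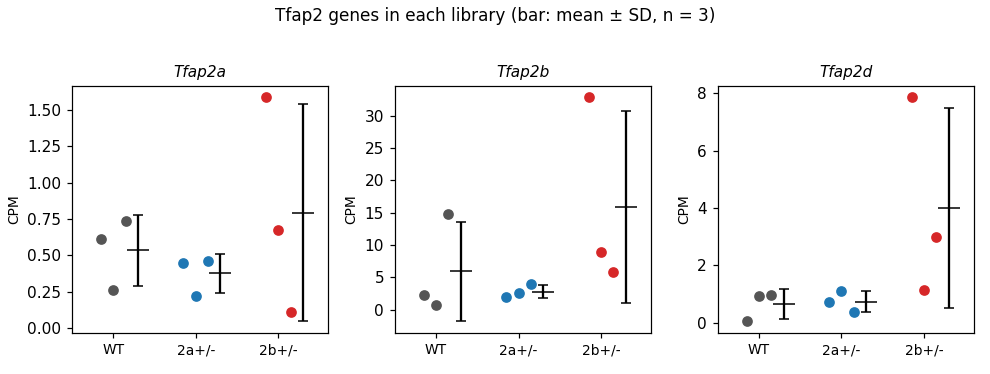
Tfap2a, Tfap2b and Tfap2d in each of the 9 libraries, in CPM on linear axes, with 1 point per library and bars for the mean ± SD of 3 libraries. Tfap2b spans 0.715 to 14.8 CPM in wild type and 5.81 to 32.9 CPM in the libraries labelled Tfap2b+/-.

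The libraries differed widely in markers of brain regions and of the ventricular lining, within genotypes as well as between them. Ttr, a thyroid hormone carrier made in bulk by the choroid plexus, ranged from 6.28 CPM in library 1 labelled Tfap2b+/- to 2761 CPM in wild-type library 2 (Ttr was chosen after its values were seen). The choroid plexus score was 3.68 in wild-type library 2 and 1.85 in Tfap2a+/- library 1, against 0.69 or less in the other 7 libraries. The hindbrain score rests on the 3 of 15 list members that passed the filter. It was 4.09 in library 1 labelled Tfap2b+/-. There Tph2, the serotonin-synthesising enzyme of the raphe and itself a member of this list, reached 40.9 CPM against at most 1.55 CPM elsewhere. The olfactory bulb score was 2.05 in library 3 labelled Tfap2b+/- and 0.37 or less in the others.

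**Figure D2:**
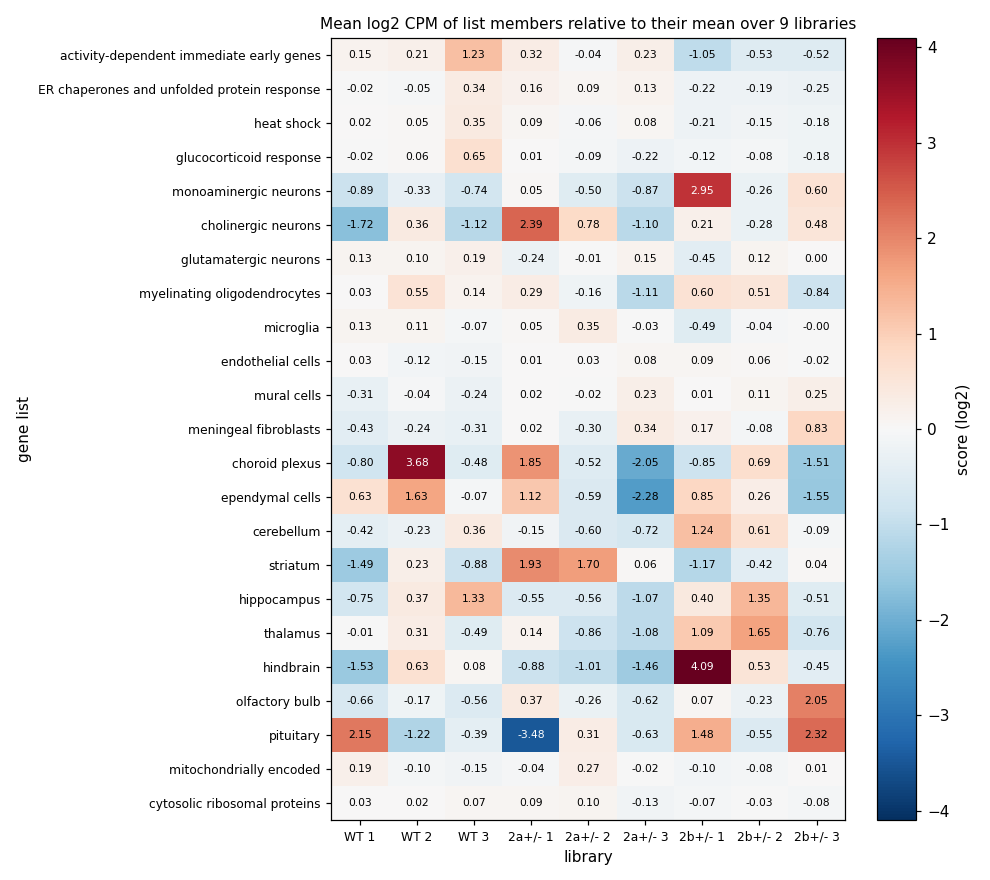
Scores of the gene lists called in any comparison, and of the hindbrain list, in each library. Rows are lists, columns are libraries (WT, wild type; 2a+/- and 2b+/-, the labelled heterozygotes), and colour and number give the mean log2 CPM of the members relative to their mean over the 9 libraries. The striatum row reads 1.93, 1.70 and 0.06 in Tfap2a+/- and -1.49, 0.23 and -0.88 in wild type.

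The libraries labelled Tfap2a+/- were compared with wild type to find which brain transcripts differ. Tfap2a+/- is the label here, since the Tfap2a counts could not settle the loss of 1 copy. Markers of the striatum, the dopamine-receiving nucleus of the basal forebrain, were higher in Tfap2a+/-: 15 of 15 measured members had a higher mean, with a median log2 fold of 2.06. Scn4b, a sodium channel beta subunit, was at 344 ± 95.2 CPM against 109 ± 23.0 CPM in wild type (SD, n = 3), a log2 fold of 1.66 ± 0.23 (SE). Pde10a, a phosphodiesterase of striatal projection neurons, was at 434 ± 201 against 108 ± 31.6 CPM. Rasd2, a small G protein of the striatum, was at 219 ± 60.2 against 93.0 ± 6.37 CPM, and Ido1, a tryptophan-degrading enzyme, at 3.36 ± 1.63 against 0.466 ± 0.444 CPM. For all 4 genes each Tfap2a+/- library lay above each wild-type library. These 4 were named for the smallest p in the list, and over all 15 members the groups did not overlap for 6. The score of the whole list did not separate the groups, since Tfap2a+/- library 3 (0.06) lay below wild-type library 2 (0.23). Camera called the striatal list (adjusted p = 9.9e-18), with adjusted p = 0.47 with an estimated correlation. No striatal member passed over all genes tested with edgeR, 11 passed adjusted over the list alone, and DESeq2 called 4.

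**Figure D3:**
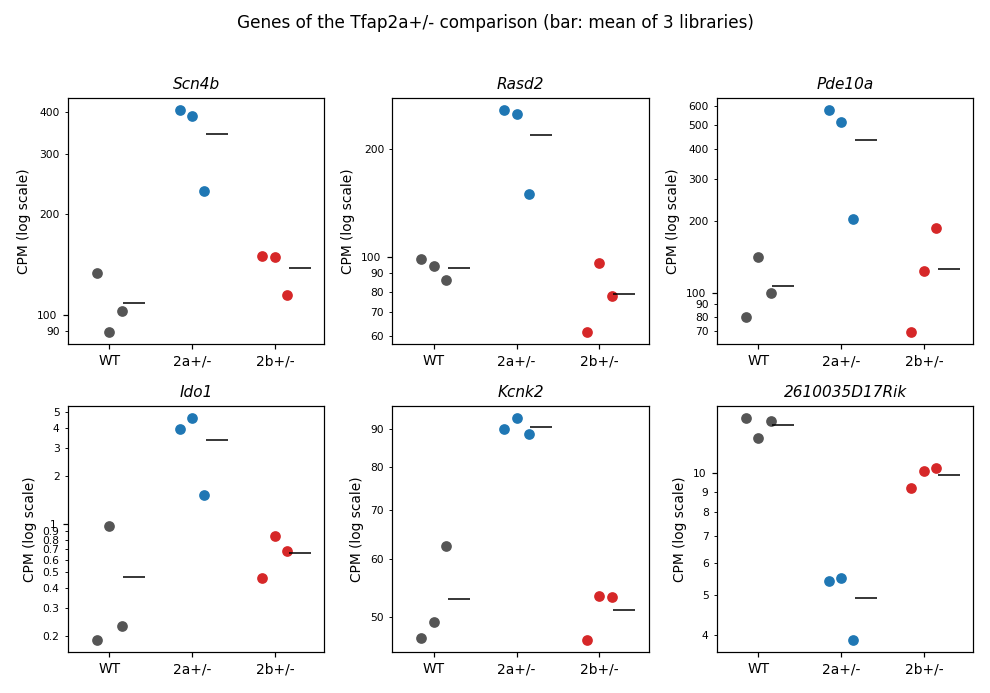
Levels in CPM, on log axes, of the striatal markers Scn4b, Rasd2, Pde10a and Ido1 and of Kcnk2 and 2610035D17Rik in each library, with bars for the mean of 3 libraries. Scn4b lies at 234 to 407 CPM in Tfap2a+/- and at 89.0 to 134 CPM in wild type.

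Other regional and cell type markers moved in the same comparison. The cholinergic neuron list was higher (7 of 8 members, median log2 fold 2.21, camera adjusted p = 0.0013), with Chat, which makes acetylcholine, at 4.77 ± 3.53 against 0.874 ± 0.799 CPM and Slc5a7, the choline transporter, at 11.7 ± 10.3 against 2.37 ± 1.65 CPM. This call ended without wild-type library 1 (median 1.86, adjusted p = 0.11) or Tfap2a+/- library 1 (median 0.95, adjusted p = 0.26). Lists of mural cells (11 of 12 members higher, median 0.26, adjusted p = 0.00098), meningeal fibroblasts (11 of 15, median 0.42, adjusted p = 0.0013) and endothelial cells (10 of 12, median 0.11, adjusted p = 0.013) were higher by camera. Examples are Vtn of pericytes at 68.1 ± 7.92 against 56.5 ± 2.39 CPM, Foxc1 of the meninges at 9.02 ± 0.879 against 6.63 ± 0.764 CPM, and Tek, the angiopoietin receptor, at 20.3 ± 1.23 against 16.8 ± 2.66 CPM. Without Tfap2a+/- library 3 the mural (median 0.19, adjusted p = 0.057), meningeal (0.17, adjusted p = 0.20) and endothelial calls (0.11, adjusted p = 0.13) ended. The meningeal call also ended without wild-type library 1 (0.25, adjusted p = 0.063) and the endothelial call without wild-type library 3 (0.070, adjusted p = 0.20) or without the 3 marker-high libraries (0.15, adjusted p = 0.064). Hippocampal markers were lower (11 of 12, median -1.28, adjusted p = 0.00098), including Spink8 of pyramidal cells at 0.361 ± 0.313 against 3.04 ± 2.04 CPM, as were thalamic markers (11 of 12, median -0.68, adjusted p = 0.026), including the transcription factor Tcf7l2 at 7.13 ± 3.97 against 20.7 ± 5.80 CPM. The hippocampal call ended without wild-type library 3 (median -0.50, adjusted p = 0.20). The thalamic call ended without wild-type library 1 or 2 or Tfap2a+/- library 2 or 3 (medians -0.60, -0.47, -0.54 and -0.55, adjusted p = 0.062, 0.20, 0.12 and 0.19). With an estimated correlation the adjusted p was 0.47 for mural cells and 0.79 for each of the other 5 lists.

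Myelin genes were lower in Tfap2a+/- (12 of 12 members, median log2 fold -0.47, camera adjusted p = 0.00098), with Mobp, a myelin structural protein, at 542 ± 250 against 784 ± 163 CPM and Mal at 169 ± 84.6 against 249 ± 38.7 CPM. Without Tfap2a+/- library 3, whose myelin score was -1.11, the median was -0.18 and the adjusted p 0.32. The median was -0.28 without wild-type library 2 and -0.81 without Tfap2a+/- library 1. Ependymal markers (11 of 11, median -0.82, adjusted p = 0.00098) and choroid plexus markers (16 of 16, median -1.70, adjusted p = 0.031) were lower. Without the 3 marker-high libraries (wild-type library 2, Tfap2a+/- library 1 and library 1 labelled Tfap2b+/-) the ependymal median was -1.60 (adjusted p = 4.7e-05) and the choroid plexus median -0.32 (adjusted p = 0.21). The ependymal call ended without wild-type library 2 (median -0.21, adjusted p = 0.073) or Tfap2a+/- library 3 (median -0.48, adjusted p = 0.20), and its median was -2.49 without Tfap2a+/- library 1. The choroid plexus median turned to 1.37 without wild-type library 2 (adjusted p = 0.28) and was -3.56 without Tfap2a+/- library 1. Its call also ended without Tfap2a+/- library 2 (median -1.34, adjusted p = 0.12) or 3 (median -1.17, adjusted p = 0.66). Kl, the gene of klotho, was at 18.7 ± 17.4 against 65.3 ± 93.6 CPM, and Dnah11 of motile cilia at 1.97 ± 2.37 against 4.91 ± 3.49 CPM. Activity-dependent immediate early genes were lower (20 of 22, median -0.52, adjusted p = 0.00098), as were glucocorticoid-responsive genes (13 of 14, median -0.30, adjusted p = 0.00098). Jun was at 45.5 ± 6.28 against 65.3 ± 15.4 CPM, and the kinase Sgk1, induced by glucocorticoids, at 47.7 ± 7.66 against 75.5 ± 26.0 CPM. Both calls ended without wild-type library 3, which had the highest score of the 9 libraries for either list (1.23 and 0.65). The medians were then -0.06 (adjusted p = 0.91) and -0.16 (adjusted p = 0.20), and the glucocorticoid median was -0.48 without wild-type library 1. Without the 3 marker-high libraries the medians were -0.82 (adjusted p = 9.5e-06) and -0.52 (adjusted p = 1.7e-05). That fit keeps wild-type library 3. It drops wild-type library 2 (scores 0.21 and 0.059), which lay below the wild-type means of 0.53 and 0.23. It also drops Tfap2a+/- library 1 (0.32 and 0.011), the highest of its group for both lists. Leaving these libraries out could only widen the difference in score, so it adds no support. With an estimated correlation the adjusted p was 0.95 for the choroid plexus and 0.79 for the other 4 lists, and no member of these 5 lists passed adjusted over the list alone.

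No single gene passed in Tfap2a+/- with edgeR, where the smallest adjusted p was 0.11. At an unadjusted p under 0.05 there were 666 genes of 17355, 374 higher and 292 lower, where chance gives about 868. DESeq2 called 30 genes, 21 higher and 9 lower, and edgeR called 3 without Tfap2a+/- library 2. In the simulations, which also held changed genes, DESeq2 called 39 unchanged genes in this design, so its calls alone do not establish changes. The 10 genes of smallest p had groups that did not overlap, as did 9.17% of all genes, where chance gives 10%. The first was 2610035D17Rik (ENSMUSG00000087259.7, chromosome 11, 113043895 to 113201838), a long noncoding RNA at 4.93 ± 0.924 CPM against 13.1 ± 0.817 CPM (log2 fold -1.41 ± 0.15). It and Scn4b were the genes that edgeR called when no filter on low counts was used (adjusted p = 0.024 each). Higher means were also seen for Kcnk2, the TREK-1 potassium channel (90.7 ± 2.36 against 52.9 ± 8.46 CPM), for Myo3b (4.11 ± 1.28 against 0.855 ± 0.145 CPM), for Clspn, an adaptor of the replication checkpoint (4.45 ± 1.95 against 0.445 ± 0.237 CPM), for the noncoding F630042J09Rik (log2 fold 1.82 ± 0.28, against 0.872 ± 0.0590 CPM in wild type) and for the Y-linked Uty (26.5 ± 2.05 against 18.9 ± 0.793 CPM). Lower means were seen for the iodide transporter gene Slc5a5 (12.9 ± 1.19 against 24.3 ± 2.43 CPM), the transcription factor Etv1 (76.7 ± 11.6 against 131 ± 14.8 CPM) and Fgf10 (5.66 ± 0.842 against 11.5 ± 2.28 CPM). Gabra5, an alpha subunit of GABA-A receptors, was at 45.1 ± 5.81 against 82.9 ± 16.5 CPM and was the member of its list that passed adjusted over the list alone. The GABA-A subunits as a list were not called (9 of 12 higher, camera adjusted p = 0.92).

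The libraries labelled Tfap2b+/- were compared with wild type in the same way. Activity-dependent immediate early genes, which neurons transcribe within minutes of firing, were lower: 22 of 22 members had a lower mean, the median log2 fold was -1.32, and for 18 members the groups did not overlap. Arc (ENSMUSG00000022602.14, chromosome 15, 74669083 to 74672570), a regulator of synaptic receptors, was at 52.8 ± 9.66 CPM against 283 ± 169 CPM (SD, n = 3), a log2 fold of -2.42 ± 0.48 (SE). The phosphatase gene Dusp1 was at 13.8 ± 0.311 against 37.9 ± 13.4 CPM, the transcription factor Egr3 at 117 ± 49.6 against 297 ± 64.0 CPM and Ier2 at 3.98 ± 0.0588 against 9.75 ± 4.16 CPM. Camera called the list (adjusted p = 3.9e-15), with adjusted p = 0.51 with an estimated correlation. No member passed over all genes with edgeR, 21 passed adjusted over the list alone, and DESeq2 called 12. The list stayed called without each of the 9 libraries in turn, and its median lay between -1.50 and -0.88, the latter without wild-type library 3.

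**Figure D4:**
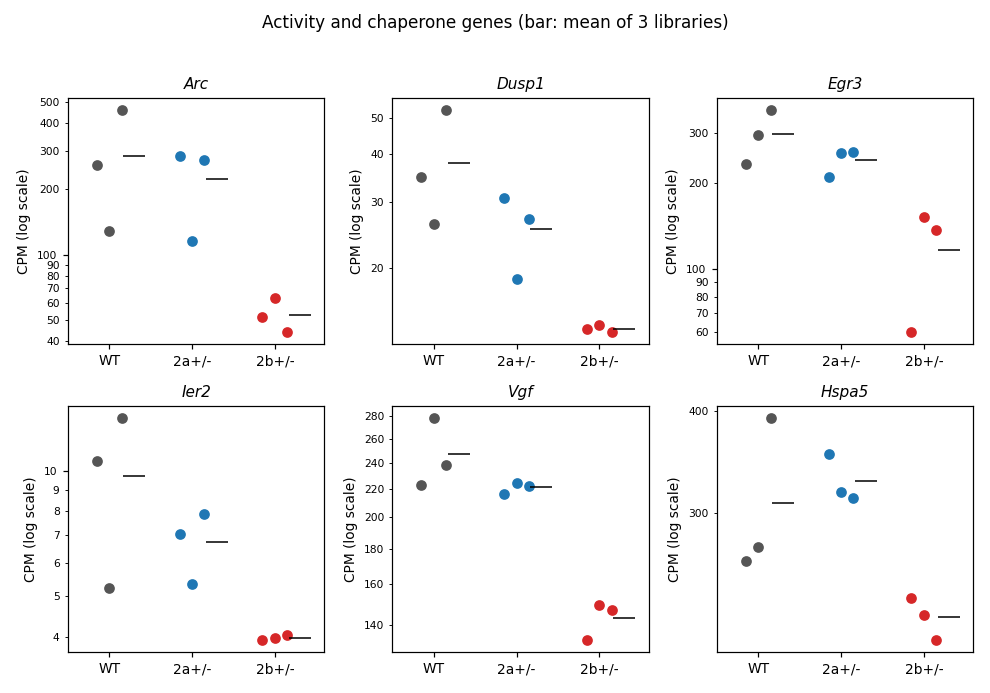
Levels in CPM, on log axes, of the immediate early genes Arc, Dusp1, Egr3 and Ier2, the activity-regulated neuropeptide precursor Vgf and the chaperone Hspa5 in each library, with bars for the mean of 3 libraries. Arc lies at 43.9 to 63.1 CPM in the libraries labelled Tfap2b+/- and at 129 to 463 CPM in wild type.

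Protein-folding genes were lower in the same libraries. Of the ER chaperones and unfolded protein response genes 17 of 17 had a lower mean, with a median log2 fold of -0.30 (camera adjusted p = 4.9e-08), and 8 passed adjusted over the list alone. Dnajb11, a cofactor of BiP, was at 38.1 ± 1.23 against 49.7 ± 5.53 CPM, Sdf2l1 at 5.01 ± 1.12 against 9.83 ± 2.91 CPM and the disulfide isomerase gene Pdia6 at 72.1 ± 1.56 against 92.6 ± 15.8 CPM. Heat shock genes were lower in 11 of 12 members (median -0.17, adjusted p = 4.5e-05), 4 of them past adjustment over the list alone. Hsph1, a cytosolic chaperone, was at a log2 fold of -0.45 ± 0.09 against 389 ± 32.7 CPM in wild type and the inducible Hspa1b at 3.64 ± 1.81 against 8.84 ± 2.22 CPM. Both lists stayed called without each library in turn, with an ER chaperone median of -0.18 without wild-type library 3, and their adjusted p was 0.67 with an estimated correlation. In fry's test for change in either direction, the smallest adjusted p over the lists was 0.039, for heat shock genes. Cytosolic ribosomal protein genes were lower in 30 of 32 members by a small amount (median -0.09, adjusted p = 0.00049), with Rps14 at 108 ± 7.09 against 127 ± 7.65 CPM. Their adjusted p was 0.72 with an estimated correlation.

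These libraries also held more reads outside annotated exons on the sense strand, 11.3% ± 0.426 of fragments against 8.01% ± 0.788 in wild type (SD, n = 3). The exact permutation test gave p = 0.1, the smallest possible. Transcripts of the TEC class, which are single-exon models that still await experimental evidence, had a higher mean in 83.0% of 512 tested, with a median log2 fold of 0.63, against 46.4% of 14756 protein-coding genes. In Tfap2a+/- 70.1% of TEC transcripts were higher, with a median of 0.19. Malat1, a noncoding RNA kept in the nucleus, was at 1195 to 1492 CPM in the libraries labelled Tfap2b+/- and at 677 to 832 CPM in wild type, and Kcnq1ot1, another such RNA, at 54.0 to 75.6 against 27.2 to 34.2 CPM. Of 5 more RNAs looked at, Meg3 (2590 to 3786 against 1243 to 2341 CPM), Snhg11 (1344 to 1681 against 624 to 1292 CPM) and Snhg14 (127 to 197 against 90.3 to 119 CPM) had groups that did not overlap, and Neat1 (38.5 to 116 against 55.0 to 64.5 CPM) and Miat (243 to 270 against 120 to 297 CPM) had groups that did. These 7 genes were chosen after their values were seen.

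Among the cell type lists, meningeal fibroblast markers were higher in the libraries labelled Tfap2b+/- (15 of 15, median log2 fold 0.62, camera adjusted p = 2.3e-05), with Slc6a20a, a proline transporter, at 26.6 ± 7.40 against 13.4 ± 3.14 CPM and the small proteoglycan Ogn at 19.1 ± 9.98 against 9.18 ± 1.91 CPM. Mural cell markers were higher (12 of 12, median 0.22, adjusted p = 0.0029), with Myh11 of smooth muscle at 24.1 ± 9.65 against 12.6 ± 2.33 CPM. Both calls held without each library in turn, with a meningeal median of 0.35 without library 3 labelled Tfap2b+/- and a mural median of 0.34 without the 3 marker-high libraries, but with an estimated correlation the adjusted p was 0.67 for meningeal and 0.51 for mural markers. Microglial markers were lower (12 of 12, median -0.24, adjusted p = 0.0016), including the complement gene C1qc at 22.0 ± 3.43 against 29.5 ± 1.26 CPM. This call ended without library 1 labelled Tfap2b+/- (median -0.083, adjusted p = 0.13) or without the 3 marker-high libraries (-0.059, adjusted p = 0.32). Glutamatergic markers were lower (13 of 15, median -0.18, adjusted p = 0.027), including Neurod6 at 66.9 ± 23.1 against 98.8 ± 13.3 CPM, and were no longer called without that library (median -0.054, adjusted p = 0.48) or wild-type library 3 (median -0.22, adjusted p = 0.090), or without the 3 marker-high libraries (-0.065, adjusted p = 0.17). Their median was -0.27 without library 2 and -0.37 without library 3 labelled Tfap2b+/-. Glucocorticoid-responsive genes were lower (14 of 14, median -0.35, adjusted p = 0.0016), including Fkbp5 at 27.8 ± 2.24 against 41.9 ± 15.3 CPM, and were no longer called without wild-type library 3 (median -0.11, adjusted p = 0.14). With an estimated correlation the adjusted p was 0.72 for the microglial and glutamatergic lists and 0.67 for the glucocorticoid list.

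Regional lists in the libraries labelled Tfap2b+/- depended in size on single libraries. Monoaminergic markers were higher (10 of 10, median log2 fold 2.78, camera adjusted p = 0.0023), but the median was 0.63 and the adjusted p 0.0501 without library 1, and the median was 1.79 without wild-type library 3. Without the 3 marker-high libraries, library 1 among them, the list stayed called (median 0.72, adjusted p = 0.030). In library 1 the serotonin transporter gene Slc6a4 reached 25.6 CPM against at most 0.566 CPM elsewhere. Th, the dopamine-synthesising enzyme, was at 11.6, 1.28 and 17.6 CPM in libraries 1 to 3 against 0.919 ± 0.142 CPM in wild type, with a log2 fold of 2.80 to 3.98 without 1 library. Th is also a member of the olfactory bulb list, whose score was highest in library 3 (2.05), so its values do not stand for monoaminergic neurons alone. Olfactory bulb markers were higher (9 of 10, median 1.43, adjusted p = 0.020) and not called without library 3 (median 0.20, adjusted p = 0.41). The median was 2.44 without library 1, 2.34 without library 2 and 2.50 without the 3 marker-high libraries (adjusted p = 0.0018). In library 3 Doc2g of mitral and tufted cells reached 10.1 CPM against at most 1.34 CPM elsewhere. Choroid plexus markers were lower (15 of 16, median -2.33, adjusted p = 0.020), but the median was 0.50 without wild-type library 2 (adjusted p = 0.99), and the call also ended without library 3 labelled Tfap2b+/- (median -2.23, adjusted p = 0.22) or without the 3 marker-high libraries (0.70, adjusted p = 0.35). With an estimated correlation the adjusted p was 0.67 for the monoaminergic and olfactory lists and 0.76 for the choroid plexus.

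No single gene passed in the libraries labelled Tfap2b+/- with edgeR, where the smallest adjusted p was 0.19. At an unadjusted p under 0.05 there were 1841 genes, 1121 higher and 720 lower, against about 868 by chance. That count was 1134 without library 1 and 2799 without library 3 labelled Tfap2b+/-, and 1051 without the 3 marker-high libraries. DESeq2 called 150, 106 higher and 44 lower, and in the simulations of this design it called 33 unchanged genes. edgeR called 2 without library 1 and 4 without library 3 labelled Tfap2b+/-. Groups did not overlap for 16.5% of genes, where chance gives 10%. The 10 genes of smallest p had groups that did not overlap. They include Vgf (ENSMUSG00000037428.14, chromosome 5, 137026392 to 137033351), the precursor of neuronal peptides, at 143 ± 8.94 against 247 ± 28.8 CPM (log2 fold -0.79 ± 0.10), and Csrnp1, a nuclear protein gene induced by axin, at 5.91 ± 0.834 against 13.8 ± 2.24 CPM. Of the predicted protein-coding genes Gm15446 and Gm14443, the former was at 10.0 ± 0.539 against 16.8 ± 2.18 CPM and the latter at 3.16 ± 0.312 against 1.20 ± 0.175 CPM. Ubn2, a histone chaperone subunit, was at 94.1 ± 5.08 against 67.4 ± 3.41 CPM. The other 5 were noncoding or pseudogene models at low levels: Tdpx-ps1 (1.13 ± 0.275 against 0.0947 ± 0.0179 CPM), 4833422M21Rik (0.808 ± 0.116 against 0.161 ± 0.0244 CPM), Gm7335 (1.49 ± 0.549 against 0.199 ± 0.0888 CPM), and the TEC transcripts Gm20371 (1.17 ± 0.0767 against 0.268 ± 0.0961 CPM) and D230049E03Rik (0.734 ± 0.0374 against 0.136 ± 0.0212 CPM). Counts of the pseudogenes are uncertain because their reads can be shared with parent genes.

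Lists tied to AP-2 and to sleep and circadian timing were not called in either comparison with wild type. AP-2 target genes and cofactors had 10 of 23 members higher in Tfap2a+/- (camera adjusted p = 0.66) and 16 of 23 in the libraries labelled Tfap2b+/- (adjusted p = 0.24). The melanocyte gene Tyrp1, the member of this list that passed adjusted over the list alone, was at 1.09, 0.573 and 4.34 CPM in the libraries labelled Tfap2b+/- against at most 0.151 CPM in the other 6. Circadian clock genes had 10 and 11 of 22 members higher (adjusted p = 0.999 and 0.37). Arntl was at 44.1 ± 7.52 CPM in Tfap2a+/- against 34.0 ± 4.96 CPM in wild type, and Csnk1d at 113 ± 2.43 CPM in the libraries labelled Tfap2b+/- against 132 ± 7.96 CPM. Sleep and wake neuropeptides and their receptors had 8 and 7 of 17 members higher (adjusted p = 0.94 and 0.67), with Adora2a, an adenosine receptor of the striatum, at 55.3 ± 34.4 CPM in Tfap2a+/- against 12.7 ± 14.8 CPM (log2 fold 2.12, and 3.68 without wild-type library 2), and Ptgds, prostaglandin D synthase, at 794 ± 186 CPM in the libraries labelled Tfap2b+/- against 485 ± 151 CPM. In Tfap2a+/- the median of the clock list (-0.06) and of the sleep list (-0.02) had the opposite sign to camera's direction. The interferon, astrocyte, oligodendrocyte precursor, GABAergic, blood, hypothalamic and oxidative phosphorylation lists were not called in either comparison with wild type (adjusted p from 0.053 to 0.92). Striatal markers had 10 of 15 members higher in the libraries labelled Tfap2b+/- (adjusted p = 0.60), and ER chaperones 12 of 17 higher in Tfap2a+/- (adjusted p = 0.52). Cerebral cortex markers had 9 of 14 members higher in Tfap2a+/- (adjusted p = 0.77) and 3 of 14 in the libraries labelled Tfap2b+/- (adjusted p = 0.070).

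The heterozygotes were also compared directly, as a test of whether their effects differ. Tfap2a+/- had higher levels than the libraries labelled Tfap2b+/- of striatal markers (15 of 15, median log2 fold 1.85, camera adjusted p = 1.6e-09), ER chaperones (17 of 17, median 0.30, adjusted p = 3.1e-09), immediate early genes (21 of 22, median 0.80, adjusted p = 1.8e-08) and microglial markers (12 of 12, median 0.31, adjusted p = 8.6e-05). Scn4b was at 344 ± 95.2 against 138 ± 19.8 CPM, Hspa5, the ER chaperone BiP, at 328 ± 22.8 against 224 ± 13.4 CPM, Arc at 223 ± 93.8 against 52.8 ± 9.66 CPM and Tmem119 of microglia at a log2 fold of 0.42 ± 0.15 against 16.2 ± 3.37 CPM (0.26 without library 1 labelled Tfap2b+/-). Thalamic markers (11 of 12, median -1.56, adjusted p = 0.00073) and cerebellar markers (9 of 12, median -0.84, adjusted p = 0.012) were lower in Tfap2a+/-, with Tcf7l2 at 7.13 ± 3.97 against 82.0 ± 71.8 CPM and Cbln1, a synaptic organiser of granule cells, at 4.39 ± 1.92 against 18.8 ± 10.6 CPM. With an estimated correlation the adjusted p was 0.63 for each of these 6 lists. Adjusted over the list alone, 13 striatal, 10 ER chaperone, 4 immediate early, 3 thalamic and 1 cerebellar members passed, and none with edgeR over all genes. These 6 lists stayed called without each of the 9 libraries. The thalamic median was -0.61 without library 2 labelled Tfap2b+/-. The microglial median was 0.15 without library 1 of that group, 0.19 without Tfap2a+/- library 2 and 0.18 without the 3 marker-high libraries. The cerebellar median was -1.69, -0.49 and -0.51 without Tfap2a+/- libraries 1, 2 and 3, and the cerebellar call ended with a filter at a mean of 1 CPM (median -0.69, adjusted p = 0.058).

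No single gene passed between the heterozygotes with edgeR (smallest adjusted p = 0.12), 1997 had an unadjusted p under 0.05, of which 864 were higher and 1133 lower in Tfap2a+/-, and DESeq2 called 208, 87 higher and 121 lower. The unadjusted count was 1096 without library 1 and 3293 without library 3 labelled Tfap2b+/-. It was 1167 without Tfap2a+/- library 2 and 1187 with a surrogate variable. Without library 3 labelled Tfap2b+/- edgeR called 31 genes, 28 of them lower in Tfap2a+/-. It called 2 without library 1 of that group and 3 without Tfap2a+/- library 2. The 10 genes of smallest p were again apart in every library. Lrrk2, a kinase abundant in the striatum, was at 110 ± 9.41 against 62.3 ± 7.90 CPM, Kcnk2 at 90.7 ± 2.36 against 51.1 ± 3.96 CPM, Rasd2 at 219 ± 60.2 against 78.5 ± 17.4 CPM, Vgf at 221 ± 4.05 against 143 ± 8.94 CPM and Gm15446 at 19.0 ± 0.333 against 10.0 ± 0.539 CPM. The metalloprotease gene Adamts19 was at 0.140 ± 0.0860 against 2.69 ± 1.02 CPM and 2610035D17Rik at 4.93 ± 0.924 against 9.87 ± 0.607 CPM. The other 3 were F630042J09Rik (log2 fold 1.88 ± 0.28, against 0.838 ± 0.0428 CPM), Gm42031 (1.04 ± 0.237 against 0.213 ± 0.0319 CPM) and Tdpx-ps1 (0.0718 ± 0.0326 against 1.13 ± 0.275 CPM).

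Both comparisons with wild type share the same controls, so their folds correlate by chance. Across 17355 genes, which are not independent replicates, Pearson's r between the log2 folds was 0.33, against 0.50 ± 0.012 (SD) in 100 simulations of unchanged groups with those controls. The covariance was 0.046 against 0.058 ± 0.0020 in the simulations, a difference of -0.012. The simulated SD leaves out the regional differences between these libraries: over 100 random regroupings of the 9 libraries r ran from -0.053 to 0.75 and the covariance from -0.0069 to 0.15, and r ran from 0.12 to 0.47 without 1 library. The observed values lay inside these ranges, so neither a shared effect nor its absence was shown. Of the genes called by DESeq2, 1 was higher in both comparisons and 1 lower in both, where independent lists would share 0.12 and 0.021. With 3 control libraries, no split leaves 2 on each side, so part of that overlap may come from the shared controls.

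Genes near the targeted loci were examined because a knockout allele can carry flanking DNA of another strain. Within 10 Mb of Tfap2a, 0 of 127 tested genes were called in Tfap2a+/- with edgeR and 0 with DESeq2, and 3.94% had an unadjusted p under 0.05, against 3.84% of other genes (two-sided Fisher's exact test, p = 0.82). Within 20 Mb DESeq2 called 2 of 281 genes in Tfap2a+/-, against 28 of the genes elsewhere (Fisher's exact test, p = 0.085). Within 10 Mb of Tfap2b, 0 of 77 genes were called in the libraries labelled Tfap2b+/- with edgeR and 1 with DESeq2, and 10 of the 77 had an unadjusted p under 0.05, against 10.6% of other genes (Fisher's exact test, p = 0.46). The median absolute log2 fold was 0.14 near Tfap2a against 0.11 elsewhere, and 0.23 near Tfap2b against 0.16. It was also larger near the locus that was not targeted. Near Tfap2b it was 0.15 against 0.11 in Tfap2a+/-, where 7.79% against 3.82% had an unadjusted p under 0.05 (Fisher's exact test, p = 0.075). Near Tfap2a it was 0.19 against 0.16 in the libraries labelled Tfap2b+/-. These medians therefore do not single out the targeted locus. Of the genes that differ between C57BL/6 substrains, Gabra2 was at 220 ± 54.5 CPM in wild type, 221 ± 9.58 in Tfap2a+/- and 189 ± 60.7 in the libraries labelled Tfap2b+/-. Nnt was at 0.238 ± 0.130, 0.238 ± 0.0706 and 0.421 ± 0.187 CPM. The substrain list was not called (camera adjusted p = 0.57 and 0.79). The Y-linked genes and Xist, at most 0.264 CPM, matched male tissue in all 9 libraries. The score over the check genes that passed the filter was -0.52 to -0.13 in wild type. It was 0.13 to 0.18 in Tfap2a+/- and 0.079 to 0.15 in the libraries labelled Tfap2b+/- (exact permutation p = 0.1 against wild type for each). The cause of this difference was not tested. Kdm5d was at 22.2 ± 1.11 CPM in wild type, 26.3 ± 1.03 CPM in Tfap2a+/- and 28.8 ± 0.700 CPM in the libraries labelled Tfap2b+/-, Eif2s3y at 18.8 ± 7.60, 32.1 ± 1.38 and 32.1 ± 3.32 CPM (log2 fold 0.77 in either comparison, and 0.48 without wild-type library 2), and Ddx3y at 65.4 ± 3.58, 72.3 ± 3.13 and 74.9 ± 8.41 CPM.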

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

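No test in this part was chosen after its own result was seen, although the immediate early and striatal patterns were known when the tests of their explanations were chosen. Camera's test between the heterozygotes found 12 lists whose 2 effects differed. The adjusted p was 1.6e-09 for the striatum, 3.1e-09 for ER chaperones, 1.8e-08 for immediate early genes, 8.6e-05 for microglia, 0.00073 for the thalamus and 0.0058 for monoaminergic neurons. It was 0.0096 for ribosomal proteins (26 of 32 members higher in Tfap2a+/-, Rpl30 at a log2 fold of 0.31 ± 0.11), 0.010 for heat shock genes (10 of 12 higher) and 0.011 for the hippocampus (10 of 12 lower, C1ql2 at 1.38 ± 1.57 against 14.5 ± 11.4 CPM). For the cerebellum it was 0.012, for mitochondrially encoded genes 0.041 (9 of 10 higher) and for the pituitary 0.042 (4 of 4 lower, growth hormone gene Gh at 5.97 ± 4.95 against 24.8 ± 18.1 CPM). With an estimated correlation no list was called, and the smallest adjusted p was 0.63. Of the 6 lists not described above, each lost its call without some library. These were the monoaminergic list without library 1 labelled Tfap2b+/- (median -0.56, adjusted p = 0.089), the hippocampus without library 2 of that group (-0.65, adjusted p = 0.15) and heat shock genes without its library 3 (0.13, adjusted p = 0.069) or Tfap2a+/- library 1 (0.16, adjusted p = 0.053). Mitochondrially encoded genes lost theirs without Tfap2a+/- library 2 (0.079, adjusted p = 0.29) or library 1 or 2 labelled Tfap2b+/- (both 0.17, adjusted p = 0.081 and 0.097). Ribosomal proteins did so without Tfap2a+/- library 1 or 2 (0.052 and 0.036, adjusted p = 0.16 and 0.17) or library 3 labelled Tfap2b+/- (0.081, adjusted p = 0.069), and had a median of 0.14 without Tfap2a+/- library 3. The pituitary list did so without wild-type library 3, Tfap2a+/- library 1 or library 1 or 3 labelled Tfap2b+/- (medians -2.09, -1.59, -1.88 and -1.44, adjusted p = 0.052, 0.14, 0.067 and 0.084). Without the 3 marker-high libraries (wild-type 2, Tfap2a+/- 1 and 1 labelled Tfap2b+/-) the hippocampal (-1.48, adjusted p = 0.058), pituitary (-1.30, adjusted p = 0.38) and ribosomal (0.026, adjusted p = 0.24) calls ended, and the monoaminergic median was -0.59 (adjusted p = 0.044). With the replicate number as a block the pituitary (-1.62, adjusted p = 0.065) and mitochondrial (0.15, adjusted p = 0.058) calls ended, and with a filter at a mean of 1 CPM the pituitary call (-2.13, adjusted p = 0.059). Reads outside annotated exons, which no comparison of genes uses, made up 11.8%, 11.1% and 11.1% of fragments in libraries 1 to 3 labelled Tfap2b+/-, above the highest wild-type library (8.86%).

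The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In Tfap2a+/- against wild type, edgeR called 0 genes in all 10 splits, 3 splits gave at least the 666 genes at an unadjusted p under 0.05 (highest other 1661), and 5 gave at least the 12 lists called (highest other 18). In the libraries labelled Tfap2b+/- against wild type, edgeR called 0 genes in all 10 splits, 1 split, the real one, reached 1841 unadjusted genes (highest other 1802), and 6 gave at least 12 lists (highest other 17). Between the heterozygotes all 10 splits gave at least 0 called genes (highest other 1), 2 gave at least 1997 unadjusted genes (highest other 2802), and 5 gave at least 12 lists (highest other 15). Splits that mix genotypes thus gave as many called lists as the real one.

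Immediate early genes were lower in the libraries labelled Tfap2b+/-, with a list score 1.23 below wild type (-1.23 ± 0.33, SE). Less cerebral cortex in the tissue piece as the whole cause was argued against, because the difference was -1.12 ± 0.37 after adjustment within groups for the cortex score. The slope on that score was imprecise (0.36 ± 0.47, SE) and markers only stand in for tissue, so a part from cortex stays open. A larger share of unspliced or nuclear RNA, read as the share outside annotated exons, may contribute. Adjusted for that share the difference was -0.82 ± 1.06, and because it separates the groups it cannot be told apart from genotype. For ER chaperones -0.31 ± 0.10 became -0.32 ± 0.34. Immediate early genes also change with handling and time of day, for which the labels give no values, and the genotype stays open as untested. Wild-type library 3 scored highest, but without it the list stayed called by camera at the preset correlation and its median was -0.88. With an estimated correlation camera did not call the list in the fit of all libraries (adjusted p = 0.51).

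Striatal markers were higher in Tfap2a+/-. If the pieces of tissue held different amounts of striatum, the folds of the 15 markers could follow the way those markers vary with the striatal score in the other 6 libraries. Pearson's r across the markers, which are not independent replicates, was 0.25 and Spearman's rho 0.16 (permutation p = 0.38 for r), which decides nothing. In those 6 libraries 14 of the 15 markers had a slope above 0. Single libraries among those 6 spanned 1.72 in the score, and the means of Tfap2a+/- and wild type differed by 1.94. A span of single libraries and a difference of means are unlike measures. Within Tfap2a+/- the scores were 1.93, 1.70 and 0.06, so they varied widely inside that group too. Dissection and an effect of genotype on striatal neurons cannot be told apart, because the labels do not say which part of the brain each sample came from.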

How the results depend on the processing

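Alternatives were planned, except that the near-locus counts and the fit without wild-type library 2, Tfap2a+/- library 1 and library 1 labelled Tfap2b+/-, the highest in choroid plexus or hindbrain scores, were added after seeing the data. edgeR's count of 0 genes (Tfap2a+/- against wild type, libraries labelled Tfap2b+/- against wild type, and between heterozygotes) stayed 0 with other size factors, a CPM filter, unstranded counts, a robust fit, 2 genotypes only and a surrogate variable. Without a filter it was 2, 0 and 7, with DESeq2 30, 150 and 208, and without the 3 libraries 0, 2 and 1; the cause was not tested. Leaving out each library gave 0 to 3, 0 to 4 and 0 to 31. With the replicate block it was 0 in each comparison. Same-numbered libraries did not pair: 3 of 9 pairs had a deviation correlation over 0.1 (-0.35 to 0.34), and 2 of 9 libraries correlated best with their own number. The 12 called lists per comparison became 0 with an estimated correlation and with fry's directional test (its test in either direction called heat shock genes in the libraries labelled Tfap2b+/-, adjusted p = 0.039), 12, 14 and 14 with the replicate block (2 of the 36 lost), 13, 14 and 10 with a mean CPM of at least 1 (2 lost), and 6 to 13, 12 to 16 and 11 to 15 without 1 library.

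The Tfap2b log2 fold in the libraries labelled Tfap2b+/- turned to -0.21 without the 3 libraries. The similarity r was 0.12 to 0.47 without 1 library and 0.31 with the replicate block. Within 10 Mb, 5 genes (Tfap2a) and 10 genes (Tfap2b) had an unadjusted p under 0.05, and DESeq2 called 1 near Tfap2b. Of 2205 alternative values of 117 results for named genes, 2116 kept direction and side of the threshold. Another 69 became called (55 with DESeq2) and 20, of 9 results, changed sign. None of those 20 was called, and the cause was not tested. No gene was called in the main fit, so no call could be lost, and keeping the side means only staying uncalled. In Tfap2a+/- without 1 library, Kl ran from -2.87 to 0.73, Tfap2b from -1.62 to 0.93, Tfap2d from -0.37 to 0.51, Gabra2 from -0.12 to 0.23 and Nnt from -0.28 to 0.49; Nnt was 0.042 unstranded, and with a surrogate variable Nnt was 0.19 and Gabra2 -0.10. In the libraries labelled Tfap2b+/-, Kl ran from -2.98 to 0.13, Tfap2a from -0.41 to 1.07 and Gabra2 from -0.48 to 0.0051. Without the 3 libraries these were 0.46, -0.74 and 0.21, and Tfap2a was -0.65 with a surrogate variable (0.59 between heterozygotes). The choroid plexus median ran from -3.56 to 1.37 in Tfap2a+/- and from -2.85 to 0.50 in the libraries labelled Tfap2b+/-, where it was 0.70 without the 3 libraries. Depth alone does not set precision: Tfap2a had 39 and 28 counts in its 2 genotypes and an SE of 0.80, Tfap2b 450 and 1351 and an SE of 0.98.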

Other observations

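The genes of this part, and the test of Tfap2b against regional scores, were chosen after the values were seen. Several processed gene copies were counted in some libraries and nearly absent from the rest. Eno1b (chromosome 18, 48045335 to 48048412) was at 21.3 and 18.9 CPM in Tfap2a+/- libraries 1 and 3 and at 0.757 CPM or less in the other 7, and Gm4735 (chromosome 2, 80837141 to 80838442) at 10.6 and 9.40 CPM in the same libraries against 0.527 CPM or less. Eno1, the glycolytic enolase, was at 298 and 301 CPM there and at 336 to 475 CPM elsewhere. Rps3a3 (chromosome 13, 108670603 to 108671397) was at 20.5 and 21.2 CPM in libraries 1 and 2 labelled Tfap2b+/- and 0.715 CPM or less in the others, while Rps3a1 was at 93.5 and 94.8 CPM there and 128 to 161 CPM elsewhere. Of the 25-base words of the annotated transcripts, 83.5% of those of Eno1b and 91.5% of those of Gm4735 occur in Eno1, and 73.5% of those of Rps3a3 occur in Rps3a1, so these counts are uncertain. Eno1b and Gm4735 were among the 3 genes edgeR called without Tfap2a+/- library 2, and Rps3a3 among the 4 called without library 3 labelled Tfap2b+/-. The noncoding Gm34672 (chromosome 13, 59235750 to 59255411) was at 0.993 to 1.66 CPM in Tfap2a+/- and 0.235 CPM or less elsewhere. It lies within 20 Mb of Tfap2a and is 1 of the 2 genes there that DESeq2 called in Tfap2a+/- (adjusted p = 0.035).

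A candidate explanation for the levels of Tfap2b is the regional make-up of each piece of tissue. Of 9 regional scores, the cerebellar one had the largest correlation with Tfap2b log2 CPM over the 9 libraries: Pearson's r was 0.78 (exact permutation p = 0.013, adjusted p = 0.12) and Spearman's rho 0.67 (exact permutation p = 0.059, adjusted p = 0.44). Without the 2 libraries farthest from the median score r was 0.48, so the relation rests partly on them. The permutation ignored genotype, so differences between genotypes can add to r. Within Tfap2a+/- the cerebellar scores of -0.15, -0.60 and -0.72 went with Tfap2b at 1.88, 2.54 and 3.96 CPM, the opposite direction. In each of the other genotypes the library of highest cerebellar score had the highest Tfap2b. For the hindbrain score, which rests on 3 genes, r was 0.62, rho 0.40 and r without the 2 libraries farthest on that score 0.053. Wild-type library 2, second in that score (0.63), had the lowest Tfap2b (0.715 CPM). No score passed after adjustment, and the explanation stays open beside an effect of the allele and a wrong label, neither of which was tested.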
